A study of Homo sapiens with 9 samples.

How the data were processed

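The 9 libraries came from HCT-116 cells, a human colon cancer line, grown untreated. The labels give HCT-116 clone number 28 for all 9. Per the labels, 3 libraries were made from the unedited line (here WT) and 3 from each of E4 and D3. E4 and D3 are single-cell clones of a CRISPR/Cas9-edited pool carrying a mutated CTCF binding site inside the colorectal super-enhancer (OSE). CTCF is a zinc finger protein that anchors chromatin loops. The labels number 3 biological replicates per group. They do not say that the replicates came from separate cultures, so p-values measure the spread between these libraries, and the clones themselves number only 1 per name.

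Per the labels' protocols, chromatin was crosslinked with 1% PFA, cut with HindIII and ligated, and the ligated DNA was tagmented, transcribed in vitro to RNA, copied to cDNA and amplified from a bait primer (Nodewalk). Reads were mapped with BWA to hg19 and to the fly build BDGP5, per the submitters' processing notes; the BWA version is not given in the sources used here. Each deposited table lists read counts per HindIII fragment and probe, split by the authors into classes named under 10, under 30 and over 30 of a quantity that the file headers do not name. The under-10 class held 0 reads and the column of molecular identifiers was 0 throughout. The deposited tables also hold counts of distinct read positions, a list of positions with their reads for positions with over 5 reads, and a probe match given as a fraction. That fraction was used to find the fragment holding each probe. No replicates were pooled in the deposited tables.

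Ligation events were counted from the listed positions. Positions on the same strand of a fragment that lay within 10 bases of the next were merged into 1 event, so 7817 listed positions gave 2862 human events with the MYC probe. Deduplicated events were chosen over reads before the data were examined. The 10-base merging rule was chosen after the files had been seen, as were the alternatives that use other merging distances, the deposited position counts, events of at least 100 reads, events at unshared positions, fragments mostly in the over-30 class, fragments with at least 4 events, and the libraries without replicate 3. Amplified reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

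The MYC bait fragment spans chromosome 8, 128745989 to 128756984 (hg19). It and its neighbours were left out of all totals, so MYC itself has no value. Library size was the number of human events. A fragment was put in a window by its midpoint. No hg19 annotation was used here: the windows for FAM84B, PCAT1, OSE, CASC8 with CCAT2 and POU5F1B, and PVT1 were fixed from textbook positions before the data were examined. The labels give a guide RNA cut at position 127215101 of chromosome 8 without naming a build. In the GRCh38 gene table that position lies in CCAT1, the long noncoding RNA gene of the super-enhancer, and it was not converted to hg19. Read as hg19, it would lie outside the OSE window of 128.15 to 128.28 Mb. The labels place the mutated site inside the OSE, which argues against hg19 as its build. Whether the cut lies in the core of the OSE window (128.21 to 128.24 Mb, hg19) or in its flanks was not determined.

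Shares per library were compared with exact two-sided permutation tests on the difference of means, in which the smaller tail is doubled. With 3 against 3 libraries the smallest p is 0.1, and with 6 against 3 it is 0.0238. Benjamini-Hochberg adjustment ran over the 9 region classes of each contrast. Region classes, 50 kb bins within 2 Mb of the bait and HindIII fragments were tested with edgeR 4.0.16 (quasi-likelihood, group as the only term, normalization factors of 1, adjusted p under 0.05), with bins and fragments kept at 10 or more events over the 9 libraries. DESeq2 1.42.0 and edgeR's TMM factors were alternatives. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Named were all fixed regions and, since no fragment passed a test, the 10 fragments on chromosome 8 and the 5 in the OSE window with the largest mean share.

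The edgeR step was tested on simulated data with 1000 bins at the measured depth, 100 raised and 100 lowered. They were drawn with counting error alone, without further spread between libraries. The real fits tested 15 bins or 9 classes, so the adjustment for multiple tests differs and the recovery there may differ too. For E4 against WT, 0% of bins raised 2-fold, 43% raised 4-fold and 100% raised 8-fold were recovered, against 0%, 8% and 11% of bins lowered by the same factors. For both clones against WT, 72% of bins raised 4-fold and 12% lowered 4-fold were recovered. In 2000 simulations of the OSE share with counting error alone, the exact permutation test of both clones against WT gave p under 0.05 in 53.5% of runs for a 2-fold rise and in 31.6% for a fall to 0.5 of the WT share. No 2 files held identical values.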

Results

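Contacts of MYC, the proto-oncogene on chromosome 8, were measured by Nodewalk in HCT-116 cells and in the E4 and D3 clones, with 3 libraries per group. The stated question was whether mutating a CTCF site in the colorectal super-enhancer (OSE) alters how often MYC meets the super-enhancer. The MYC probe had between 3193787 and 6656618 reads per library. These reads represented few ligation events: 187, 477 and 171 in WT replicates 1 to 3, 392, 529 and 182 in E4, and 247, 514 and 163 in D3. Of the 2621 human fragments with events, 2471 had 1 event over all libraries.

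Per kb, the OSE window was contacted more densely than the other fixed windows around MYC. It spans fragments from 128153493 to 128282585 on chromosome 8 (hg19), 466 to 592 kb upstream of the probe, and held 60 events over the 9 libraries, or 46.5 per 100 kb of that span. The window of CASC8, CCAT2 and POU5F1B, which lies nearer to MYC, had 29.1 per 100 kb. PVT1, the noncoding RNA gene downstream of MYC, had 22.8 per 100 kb, and the PCAT1 side of the super-enhancer had 6.42. The windows also differed in how densely fragments lay. The OSE had its 60 events on 27 listed fragments, and the CASC8 window had 58 on 33. PVT1 had 73 on 39, and the PCAT1 side had 15 on 17. The ranking thus holds per kb, and no test compared the windows. Within the OSE, the core fragments from 128207867 to 128241347 had 26 events, or 77.7 per 100 kb. Among 50 kb bins within 2 Mb of the bait, the bin from 128200001 to 128250000 ranked 1 with 33 events over the 9 libraries. It also led in WT with 11 and in E4 with 15. In D3 it held 7, fewer than the 9 in the bin from 128250001 to 128300000.

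**Figure D1:**
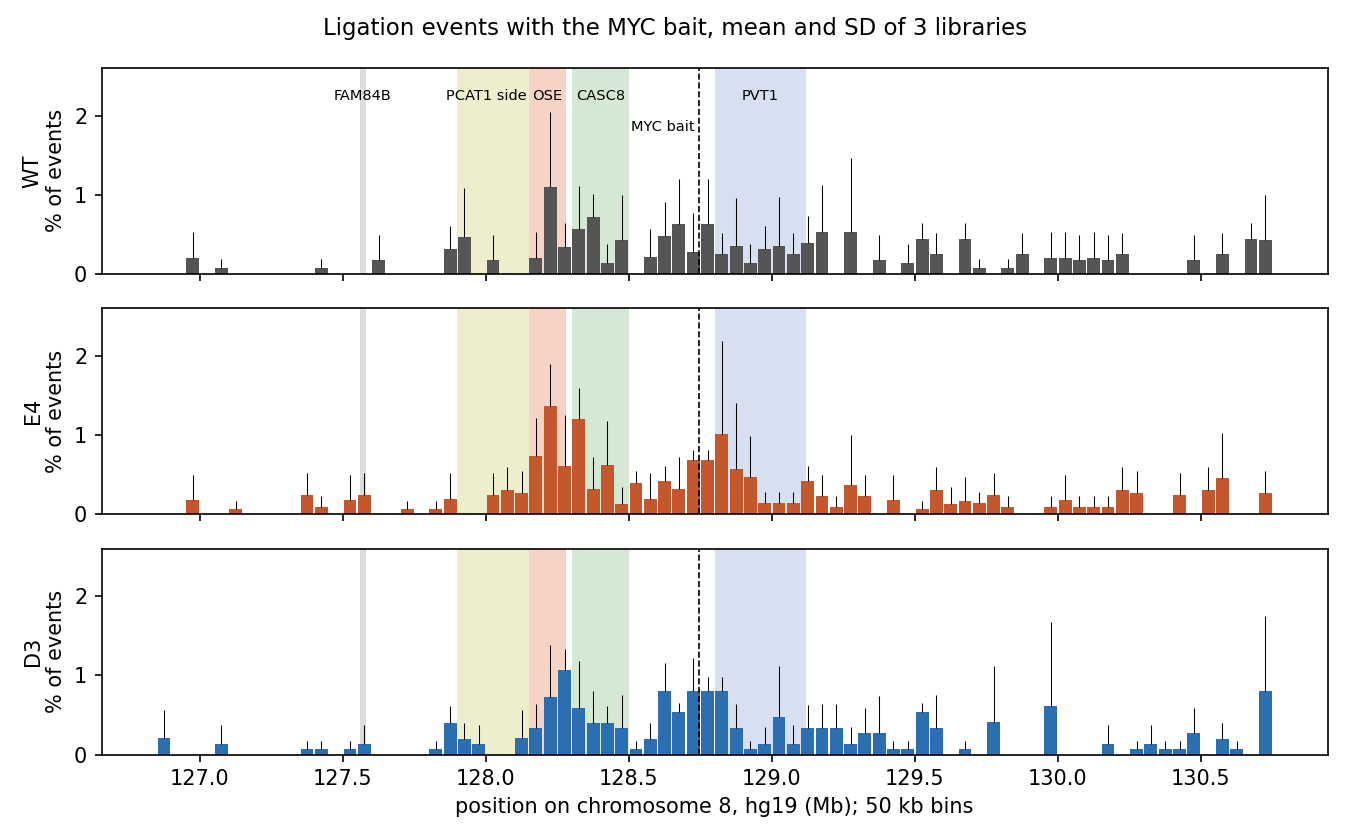
Share of human ligation events (y axis, percent) per 50 kb bin on chromosome 8 (x axis, hg19 Mb) for WT, E4 and D3; bars are means of 3 libraries, lines the SD above them, shaded bands the fixed windows, and the dashed line the MYC probe. The bin starting at 128200001 holds 33 events over the 9 libraries.

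In E4, 2.51% ± 0.479 (SD, n = 3) of events fell in the OSE window, against 1.55% ± 0.361 (SD, n = 3) in WT. The 3 E4 libraries all lay above the 3 WT libraries, a difference of 0.956 percentage points. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries can give, and 0.9 after adjustment over the 9 classes. The counts were 12, 12 and 4 events in E4 and 3, 9 and 2 in WT. The edgeR log2 fold change was 0.60 (SE 0.48, 95% interval -0.43 to 1.63, adjusted p = 0.972). The difference turned to -0.197 points with reads in place of events (exact permutation p = 0.8), and fell to 0.321 points with the deposited position counts (exact permutation p = 0.7).

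In D3, 2.08% ± 0.933 (SD, n = 3) of events fell in the OSE window, with 3, 10 and 5 events in replicates 1 to 3. This was 0.522 percentage points above WT, within the spread between libraries (exact permutation p = 0.4). The edgeR log2 fold change was 0.23 (95% interval -0.89 to 1.35, adjusted p = 0.984). The difference was -0.732 points with reads (exact permutation p = 0.2) and -0.165 points without the 3 libraries of replicate 3 (exact permutation p = 1). D3 minus WT was -0.39, 0.0587 and 1.9 points in replicates 1 to 3, and E4 minus WT was 1.46, 0.382 and 1.03 points. The 3 libraries of replicate 1 share a run label in the files, and each of the others has its own.

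Both clones together had 2.29% ± 0.705 (SD, n = 6) of events in the OSE window, 0.739 percentage points above WT (exact permutation p = 0.143). The edgeR log2 fold change was 0.42, with a 95% interval from -0.54 to 1.37 (adjusted p = 0.984), which corresponds to 0.689 to 2.58 times the WT share. That interval holds for events only: the difference was -0.465 points with reads (exact permutation p = 0.524) and 0.244 points with the deposited position counts (exact permutation p = 0.69). The OSE core went the other way: its share was 0.749% ± 0.511 (SD, n = 6) in the clones and 1.09% ± 0.948 (SD, n = 3) in WT (exact permutation p = 0.476). D3 and E4 did not separate in the OSE window (edgeR log2 fold change -0.37, adjusted p = 0.912).

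**Figure D2:**
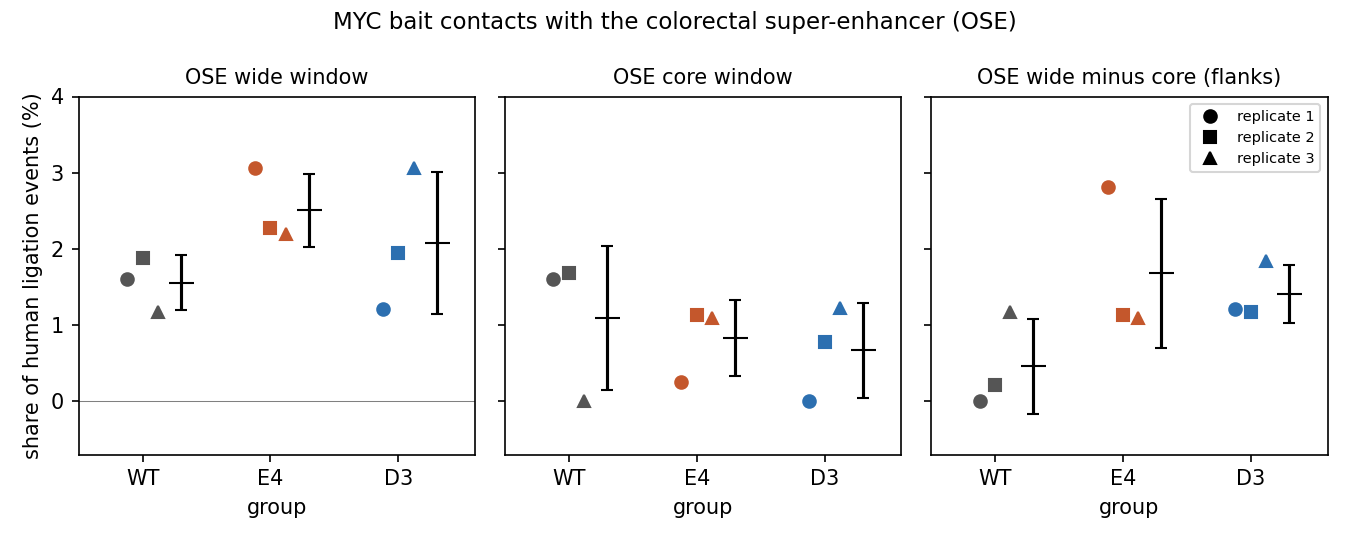
Share of human ligation events (y axis, percent) per library in the OSE window, its core and the flanks around the core, by group (x axis); symbols mark replicates and bars the mean with its SD (n = 3). The E4 libraries lie above the WT libraries in the wide window, where the means are 2.51% and 1.55%, while the core mean is 1.09% in WT.

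No fixed region, the OSE window included, passed an exact permutation test in any contrast, and 3 against 3 libraries could not give a p under 0.1. PVT1 took 1.98% ± 1.73 of events in WT, 2.59% ± 2.99 in E4 and 2.13% ± 0.822 in D3 (SD, n = 3 each). PVT1 counts depended on the replicate: replicate 3 had 2 PVT1 events among 516, against 71 among 2346 in the other replicates. The CASC8, CCAT2 and POU5F1B window took 1.85% ± 1.12 in WT, 2.27% ± 0.481 in E4 and 1.73% ± 0.439 in D3. Its D3 minus E4 difference of -0.535 points exceeded the SD of either group (exact permutation p = 0.3). The PCAT1 side took 0.638% ± 0.488 in WT, 0.824% ± 0.731 in E4 and 0.539% ± 0.314 in D3. FAM84B had 0 events among 835 in WT, which allows a share of up to 0.359%, 2 among 1103 in E4 and 1 among 924 in D3. The lowest adjusted p of an exact permutation test over these classes was 0.9.

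Across region classes and bins, edgeR called 0 changes at an adjusted p under 0.05 in any of the 4 contrasts. Of the 9 classes, 0 had an unadjusted p under 0.05 with edgeR or DESeq2. Of the 15 bins, 1 did for E4 against WT and 1 for both clones with edgeR, against 2 and 1 with DESeq2, which also called 0. The edgeR bin was 128800001 to 128850000 at the start of PVT1, with 13 events in E4, 8 in D3 and 2 in WT. Its log2 fold change in E4 was 2.12 (SE 0.99), with an edgeR adjusted p of 0.514. The bin's share was 1.02% ± 1.17 in E4, 0.799% ± 0.18 in D3 and 0.248% ± 0.269 in WT (SD, n = 3 each). In E4 the SD exceeded the mean, so the E4 libraries were uneven. No HindIII fragment reached 10 events, so 0 fragments were tested as planned; without the filter, edgeR and DESeq2 called 0 of 2621, with at most 3 fragments per contrast at an unadjusted p under 0.05. With no calls, overlap between the clones could not be computed.

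Single fragments had few events. The largest mean share on chromosome 8 belonged to an OSE core fragment, 128233029 to 128235184, with 4 events in WT, 2 in E4 and 1 in D3. The fragment 128207867 to 128226110, which ends the core upstream and holds the OSE probe, had 4, 3 and 1. Outside the core, OSE fragments 128256929 to 128263239 and 128263614 to 128270204 had 1 and 1 events in WT, 2 and 3 in E4, and 3 and 1 in D3. The short core fragment 128235178 to 128236036 had 1, 2 and 2. The remaining fragments with the largest shares lay at 129568823, 128693153, 128342867 in the CASC8 window, 129107575 and 128822636 in PVT1, and 127873159, with 4 to 7 events each.

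Contacts with other chromosomes made up most events: 72.8% ± 3.56 in WT, 70.7% ± 2.36 in E4 and 71.2% ± 4.58 in D3 (SD, n = 3 each; exact permutation p = 0.429 for both clones against WT). Fly fragments, which can only be background in these human cells, took 0.525% ± 0.585 of events in WT, 0.188% ± 0.326 in E4 and 1.06% ± 0.802 in D3. D3 lay above E4 in this background in all 3 libraries (exact permutation p = 0.1, adjusted 0.9). Of events on chromosome 8, 47.4% ± 14.2 in WT lay over 2 Mb from the probe, against 41% ± 3.87 in E4 and 43.4% ± 2.26 in D3. Thinned to 163 events, libraries held 161 ± 0.252 distinct fragments in WT, 162 ± 0.741 in E4 and 162 ± 0.407 in D3 (exact permutation p = 0.143 for both clones). Since 2471 of the 2621 fragments had 1 event over all libraries, this measure was near its ceiling of 163 in every library. It could therefore show little difference in breadth.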

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

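Rows of the OSE probe and of PhiX were outside the comparisons and exceeded the WT libraries in some clone libraries. The OSE probe had 113 reads in D3 replicate 2, against at most 103 in WT, in replicate 3. Of the 113 reads, 56 lay on the MYC bait fragment and 3 on the OSE probe's own fragment. Of the 52 fragments listed for this probe in that library, 47 were also listed for the MYC probe. That library was also deeper, with 6656618 MYC-probe reads against 6088878 in WT replicate 3. The excess is therefore no measure of contacts of the OSE. The probe in the CTCF gene did not exceed the highest WT library in any clone library: it had 1053, 456 and 0 reads in WT replicates 1 to 3 and at most 39 in a clone library. PhiX, the sequencing control, had 3 reads in E4 replicate 2, 1 in E4 replicate 3 and 2 in D3 replicate 3, against 0 in WT. Groups of 3 libraries were not tested for outliers.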

How the results depend on the processing

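Alternatives described as chosen after seeing the data in the processing account are used here beside the planned ones. The counts of changed regions, bins and fragments were 0 in all 188 contrasts and settings fitted. In simulation with counting error alone, bins lowered 4-fold were mostly missed. At most 2% of bins changed 2-fold and 43% to 72% of bins raised 4-fold were recovered. These zeros thus say little about losses or about 2-fold rises, and a 4-fold rise could also be missed. The rise in the OSE window share did not hold under several choices, and the causes were not tested. With reads it turned to -0.197 points in E4, -0.732 in D3 and -0.465 in both clones, and the edgeR log2 fold changes to -0.16, -0.70 and -0.43. With the core window it was -0.264, -0.425 and -0.345 points. Without replicate 3, D3 was at -0.165 points and a log2 fold change of -0.082, and both clones at 0.377 points. With single-event fragments left out, D3 was at -10.6 points, on at most 19 events per library, and E4 replicate 3 had none left, which gave no value for E4. Both clones passed 0.05 at 0.94 points without the window's largest fragment (exact permutation p = 0.0476) and at 0.955 points without D3 replicate 1 (p = 0.0357). These are 2 of 25 alternatives, whose p ranged up to 0.69. Leaving out 1 library gave 0.68 to 1.12 points in E4, 0.0265 to 0.953 in D3 and 0.547 to 0.955 in both, and log2 fold changes for D3 from 0.024 to 0.48. Direction was kept in 20 of 22 alternatives for E4, 19 of 23 for D3 and 23 of 25 for both; with 3 against 3 libraries no alternative could pass 0.05.

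With the replicate block the differences stayed at 0.956, 0.522 and 0.739 points (exact permutation p = 0.25, 0.75 and 0.296; 0.25 is the smallest that 3 pairs can give), and calls stayed at 0. Same-numbered libraries correlated from -0.15 to 0.312 in their deviations, and 4 of 9 libraries correlated best with their own number. The ratio to fly events was not run, since 3 libraries had 0, nor, for fragments, was the filter of 30 events, the other bait and library size rules or leaving out single libraries, since no fragment passed the count filter. Unfiltered fragments could not be fitted with TMM factors.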

Other observations

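All tests in this part were chosen after the results they bear on had been seen.

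The OSE window stood above distance alone. The mirror window of 130 kb at the same distance downstream of MYC (129223806 to 129340053) had 13 events over the 9 libraries, against 60 in the OSE window. The shares were 0.579% ± 0.602 and 2.05% ± 0.693 (SD, n = 9), and the OSE share was higher in 8 of 9 libraries (two-sided exact sign-flip permutation p = 0.00781). Distance from the bait alone predicts equal shares, which the data argue against; sequence mappability and HindIII site density were not tested.

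Inside the OSE window, the mean share of events in the flanks around the core was higher in the clones, without passing a test by library. The flanks held 3 of 14 window events in WT and 31 of 46 in the clones. By library the flank share was 0.46% ± 0.624 (SD, n = 3) in WT and 1.54% ± 0.678 (SD, n = 6) in the clones, with an exact permutation p of 0.0952. Of the 84 splits of the libraries, 9 gave a difference as large as the real 1.08 points, 4 in its direction and 5 in the other, the highest other being 1.16, so chance is not excluded. The p is the smaller tail doubled, and so differs from that share. The difference was 1.1 points without events at shared break positions and 0.831 without E4 replicate 1. Both stayed above the bound of 0.542 set first. The bound was then tightened, after these values had been seen, to require a p under 0.05 as well. The exact permutation p was 0.119 and 0.143, so neither passed the tightened bound. The pattern with all libraries had not passed 0.05 either (exact permutation p = 0.0952), so these tests exclude neither explanation. A shift of MYC contacts from core to flanks after the CTCF mutation may be a hypothesis for deeper libraries; without other clones it cannot be separated from clonal origin.

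Some ligation break positions recurred between libraries, 133 of 2878 events in all. On fragments found in both libraries of a pair, positions coincided for 72 of 145 fragments within replicates 2 and 3. In pairs with replicate 1 they coincided for 6 of 135 (two-sided Fisher's exact p = 7.48e-19, fragments taken as independent). Each library enters several pairs, so the fragments are not independent. That p is too small and does not measure the spread between libraries. Sites that recur in any library, by mispriming or preferred breakage, would coincide in both kinds of pair. The weaker copy had a median of 0.332 times the reads of the stronger, but only copies with over 5 reads enter this ratio. Of the fragments with fewer reads on other chromosomes, 116 of 4396 had an event in another library, from 33 of 262 in WT replicate 3 and 28 of 262 in WT replicate 1 down to 4 of 500, 3 of 800 and 1 of 891 in replicate 2 of WT, E4 and D3. Such weak copies were thus rare in replicate 2, which holds much of the coincidence, and index cross-talk was not settled by these values. On other chromosomes, coincident events averaged 3 per pair within replicates 2 and 3 and 0.0952 in the other pairs. They were uneven: the 5 pairs with WT replicate 2 held 29 of the 45, 4 of the 15 pairs had 0, and without WT replicate 2 the average was 1.6 against 0.111 (one-sided exact permutation p = 0.0179, the smallest that 56 choices can give). With all libraries the excess was the highest of 84 choices of 3 libraries (one-sided exact permutation p = 0.0119, the smallest they can give), consistent with carry-over of material between some of those libraries. The libraries of replicate 1 share a run label and each of the others has its own, so run and replicate are not separated. The pairs within replicate 1 had 0, 1 and 0 such events on other chromosomes, against 45 in the pairs within replicates 2 and 3. These counts cover only copies with over 5 reads. Of the fragments with fewer reads in replicate 1, 28 of 551 in E4 and 11 of 432 in D3 also had an event in another library, beside the 28 of 262 in WT. These values do not say which other library that was. Cross-talk within a run is therefore not settled by them, even if the label names the sequencing run. What the label names was not checked, and no biological explanation was tested.

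Replicate 3 had 0.388% of its events in PVT1, against 4.36% in replicate 1 and 2.3% in replicate 2. Both of its 2 PVT1 events were in D3. Of its chromosome 8 events, 0 of 41 in WT and 2 of 55 in E4 lay under 0.1 Mb from the probe, but 5 of 55 in D3, or 9.09%, which was within the range of the other replicates. Counting error alone does not account for the PVT1 share if events are independent (two-sided Fisher's exact p = 0.000141 against the pooled events of replicates 1 and 2). That p does not measure the spread between libraries. Their PVT1 shares ran from 2.83% to 5.87% in replicate 1, from 1.89% to 2.73% in replicate 2 and from 0% to 1.23% in replicate 3. Random ligation diluting all contacts alike would lower the OSE share as much, but that share was 1.02 times that of the other replicates (95% interval 0.479 to 1.99), while PVT1 was at 0.128 times. Differences in handling between replicates stay open, and no biological explanation was tested.

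For the edgeR counts of 0 changed classes and bins, the count over other splits of the libraries carries no information, since every split reaches 0: 10 of 10 splits in each comparison of 2 groups and 84 of 84 for both clones against WT. The highest count in another split was 1 for classes in E4 against WT and 1 for classes and for bins in both clones against WT, and 0 in the other comparisons.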
